A study of Mus musculus with 4 samples.

How the data were processed

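RNA was profiled in the mouse mammary epithelial line Comma D beta, per the labels. Cells were cultured overnight in DMEM F12 with 2% serum, insulin at 5 ug/ml and EGF at 10 ng/ml, and doxycycline (dox) at 100 ng/ml was then added for 1 day. Treated and untreated cells were stained for the surface marker Sca1, and 200k Sca1+ and 200k Sca1- cells were sorted. Total RNA (50 to 500 ng) was labelled with biotin by an Affymetrix 3' IVT protocol, which primes from the 3' end of transcripts. Each of the 4 combinations of dox and Sca1 is represented by 1 array. What dox controls in these cells is not given in the sources used here, although the series title names Bcl11b.

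The deposited table gives a log2 expression level for 45101 probe sets on each array. The authors' summarization, scaling and software are not given in the sources used here. On every array the deposited values share an exact minimum of 3.32, the log2 of 10, so linear levels under 10 had been set to 10. Between 44.8% and 48.0% of probe sets lay at this floor on each array, and 16490 lay there on all 4. A difference between a measured value and a floor value is therefore a lower bound, written here as "at least". The arrays' medians ran from 3.48 to 3.70, and among probe sets with a mean level of 100 or more the array medians ran from 8.20 to 8.24. The sorted values of the arrays were not identical, so the table was not quantile normalized at the level of probe sets. The 3' minus 5' difference of the actin control probe sets was 0.69, 0.81, 0.83 and 0.91 on the untreated Sca1+, untreated Sca1-, dox Sca1+ and dox Sca1- arrays, and that of the Gapdh control probe sets lay between -0.10 and 0.11.

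Genes were named from a platform annotation that lists 35890 of the probe sets, 34958 of them with 1 gene symbol and 932 with several. The remaining 9211 probe sets had no symbol in that annotation and were not named. The symbols match a mouse gene table of assembly GRCm38.p6, through which older symbols in the gene lists were updated. No coordinates are given, because the array files name no genome build. Each gene was represented by its probe set with the highest mean over the 4 arrays, which gave 18194 genes. Of these, 12264 had at least 1 array at or above the pooled median of all probe sets (3.63 on the log2 scale) and were analysed, and 10261 of the 12264 lay above the authors' floor on all arrays. The gene that encodes Sca1 had no named probe set and was not analysed here. The Sca1+ and Sca1- groups therefore follow the labels and were not checked on the expression of their marker.

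Differences of log2 levels were computed for dox against untreated cells within the Sca1+ and within the Sca1- fraction, and for Sca1+ against Sca1- cells without and with dox. The members of each pair of differences share no array. With 1 array per group there is no replicate spread, so no difference has a replicate check. Genes were counted by a rule of size, 2-fold or more (an absolute log2 difference of 1), and as shared when this held in the same direction in both differences of a pair. A yardstick for array noise was taken from the difference between the 2 dox effects, which combines 4 arrays and holds any true interaction as well as noise, so it cannot be used to judge the interaction itself. Its spread in 20 bins of mean level was used to simulate 100 sets of 4 arrays without any effect. This noise does not cover differences between cultures, since the fractions of a treatment may come from 1 culture. On simulated data with 200 changed genes among 12264, the rule for a shared dox effect found 26.0% of genes changed by 1 log2 unit, 86.0% of those changed by 1.5, 92.0% of those changed by 2 and 88.0% of those changed by 3, and called 4 of 12064 unchanged genes. The losses at the largest change were among low genes: with a mean level of 100 or more, all genes changed by 2 or 3 log2 units were found, which is 100% of each.

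For 30 gene lists, the median log2 difference was set against 10000 random lists of the same size matched on mean expression, and its percentile is given. A list at or beyond percentile 2.5 or 97.5 is described as standing apart. Random lists can do so too, and percentiles describe these arrays and are not p-values. Genes are not independent of each other, so members of a co-expressed list move together more than random genes do. The lists covered Bcl11b and its paralogue, Ly6-family, basal, luminal, milk-protein, S-phase, G2/M, growth-arrest, p53-target, ribosome-biogenesis, mesenchymal, interferon-stimulated, MHC class I, Wnt-target, Notch, TGF-beta/BMP, immediate-early, NF-kB, cholesterol, ATF4-target, ER-chaperone, heat-shock, hypoxia/glycolysis, respiratory-chain and stem/progenitor surface genes, and markers of T cells, leukocytes, fibroblasts, endothelium and adipocytes. Groups, lists, the size rule, the rule for named genes and the main alternatives were fixed before the data were examined. That rule, from which the text draws, named Bcl11b; for dox and for Sca1 the 12 higher and 12 lower genes with the largest smaller-of-2 difference among shared genes; the 5 highest and 5 lowest genes for the difference of the dox effects; the 3 highest and 3 lowest of each single difference; and up to 4 members per list with the largest mean difference, or 6 for lists standing apart. The gene that encodes Sca1 was also to be named, but had no named probe set here. Predicted genes and clone names were passed over. Ranks among genes at the floor have no order, because only a bound is known.

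The alternatives were quantile normalization, centring on array medians, no floor, stricter floors, the mean of a gene's probe sets, every probe set on its own, 1.5-fold and 3-fold rules, and an additive limma fit with dox and Sca1 as terms. The fit leaves 1 residual degree of freedom per gene, uses the interaction as its error and takes the fractions as separate samples. Pseudocount alternatives were not run, since the deposited values were already on the log2 scale. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1 were used.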

Results

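Gene expression was measured in Sca1+ and Sca1- cells sorted from the mammary epithelial line Comma D beta, with and without dox at 100 ng/ml for 1 day. The layout gives 4 arrays, 1 for each combination of Sca1 and dox. It allows the effect of dox to be read in each fraction, the Sca1+ to Sca1- difference to be read with and without dox, and the dox effects of the fractions to be compared. No group has a replicate, so the differences below carry no replicate error, and the depth of an array is set by the authors' floor at a linear level of 10. Across the 12264 genes analysed, arrays of the same treatment correlated at 0.97 (Pearson r across genes, untreated pair) and 0.97 (dox pair), and arrays of different treatment at 0.89 to 0.92.

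Bcl11b, a zinc-finger transcription factor of T-cell, skin and neuronal development and the gene named in the series title, was much higher on both dox arrays. Its most intense probe set, 1450339_a_at, read 6.87 (log2) in untreated Sca1+ cells and 12.11 with dox, a 37.9-fold difference, and 6.29 against 11.99 in Sca1- cells, a 52.0-fold difference. The other 3 Bcl11b probe sets did not share this direction. Probe set 1435227_at went from 7.52 to the floor in Sca1+ cells, at least 18.3-fold lower with dox, and from 6.21 to 5.38 in Sca1- cells. Probe set 1452966_at was at least 5.77-fold lower with dox in Sca1+ cells and 1.98-fold lower in Sca1- cells. Probe set 1438784_at was at the floor on every array except untreated Sca1+, where it read 4.90. Bcl11a, its paralogue, had a dox difference of -1.71 (log2) in Sca1+ and -0.89 in Sca1- cells. The list of these 2 genes has a median mean dox effect of 2.09 (percentile 99.4) and a median mean Sca1 difference of -0.20 (percentile 21.1), which rest on Bcl11b and Bcl11a going apart. With the probe sets of each gene averaged, its dox median was -0.36 (percentile 26.2). Untreated Sca1+ cells had 1.49 times the Bcl11b level of untreated Sca1- cells by 1450339_a_at and 2.48 times by 1435227_at.

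**Figure D1:**
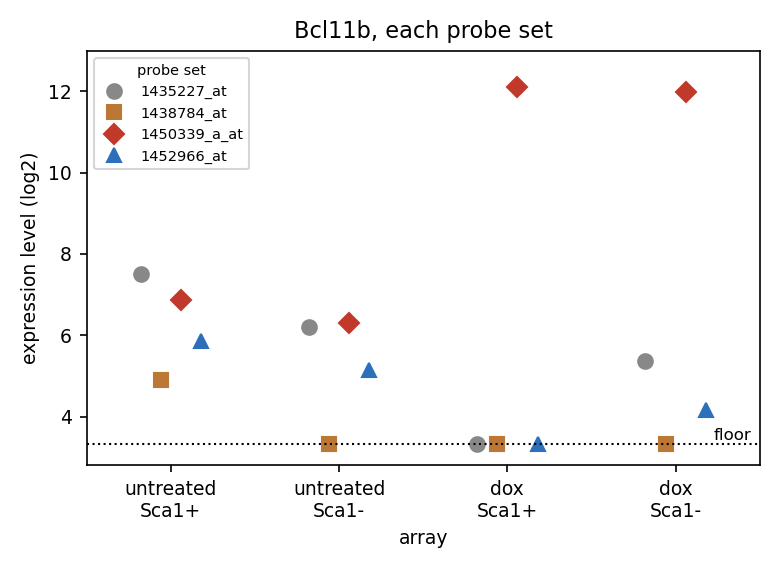
Expression level (log2, vertical axis) of the 4 Bcl11b probe sets on each of the 4 arrays (horizontal axis), with 1 point per probe set and array and the authors' floor as a dotted line. Probe set 1450339_a_at lies near 12 on both dox arrays, while the other probe sets lie lower with dox than without it or at the floor.

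Dox was accompanied by large differences that were alike in the fractions. In Sca1+ cells 1039 genes were at least 2-fold higher and 1581 at least 2-fold lower with dox; in Sca1- cells 883 were higher and 1383 lower. In the same direction in both fractions, 649 genes were higher and 1050 lower, and 2 genes were 2-fold different in opposite directions. Independent lists of these sizes would share 74.8 higher and 178 lower genes, and simulated arrays with noise alone gave 0 to 9 shared genes of either direction. Neither figure covers a difference between the treated and untreated cultures that both fractions share. Across genes, which are not independent replicates, the dox differences of the fractions correlated with Pearson r = 0.85 and Spearman rho = 0.79. Centring the arrays on the median of all probe sets, which lies next to the floor, moved the share of higher genes in Sca1+ cells from 39.7% to 27.3%. In the additive limma fit, 1460 genes were higher and 1817 lower with dox at a Benjamini-Hochberg adjusted p under 0.05; that fit treats the fractions as separate samples, although they may come from 1 culture per treatment.

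The genes with the largest dox increase seen in both fractions included several of stratified epithelium. Sprr1a, Lce1f and Scel encode precursors of the cornified envelope of keratinocytes. Sprr1a was 103-fold higher with dox in Sca1+ cells and 102-fold higher in Sca1- cells. Lce1f was at least 166-fold and at least 89.5-fold higher, and Scel 44.5-fold and 33.3-fold higher. Krt15, a basal keratin of stratified epithelia, was at least 118-fold higher in Sca1+ and 51.9-fold higher in Sca1- cells. Among secreted proteins, the collagenase gene Mmp13 was at least 153-fold higher in Sca1+ and 105-fold higher in Sca1- cells, the proteoglycan gene Dcn at least 68.0-fold and at least 34.2-fold, and Plat, the tissue plasminogen activator, 29.6-fold and 33.1-fold. A second, dimmer Dcn probe set had a mean dox effect of only 0.29 (log2). Here and below, smaller values from other probe sets are given for some genes, not for all. The interferon-inducible gene Ifi27l2a was 62.8-fold higher in Sca1+ and at least 77.1-fold higher in Sca1- cells. Dynap was 63.9-fold and 66.4-fold higher, the aldehyde oxidase gene Aox4 at least 28.4-fold and at least 37.5-fold, and Akr1c18, which inactivates progesterone, 35.3-fold and 26.6-fold.

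Among the genes lower with dox, Hp, the haemoglobin-binding acute-phase protein haptoglobin, was at least 19.8-fold lower in Sca1+ cells and 25.9-fold lower in Sca1- cells. Bmper, a BMP-binding secreted protein, was 17.8-fold and 20.4-fold lower, and Fam20a 14.9-fold and 19.6-fold lower. The neurotrophic ligand gene Artn was at least 34.8-fold and 13.6-fold lower, Fads3 at least 57.3-fold and 13.5-fold, and the carbonyl reductase gene Cbr2 28.1-fold and 13.3-fold. The matrix genes Fbln2 (21.1-fold and 12.2-fold lower) and Pcolce (at least 14.6-fold and at least 12.7-fold lower) were also in the set. Tmem54, Eif4e3, Mgam and Vnn1 completed the named set, between 10.5-fold and 12.1-fold lower in Sca1- cells, where Eif4e3 is given by its bound of 11.7. Tgfbi and Tubb6, among the 3 lowest genes in Sca1+ cells, were 47.0-fold and 49.0-fold lower there and 10.5-fold and 5.87-fold lower in Sca1- cells. A second, dimmer Tubb6 probe set had a mean dox effect of only -0.20 (log2).

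**Figure D2:**
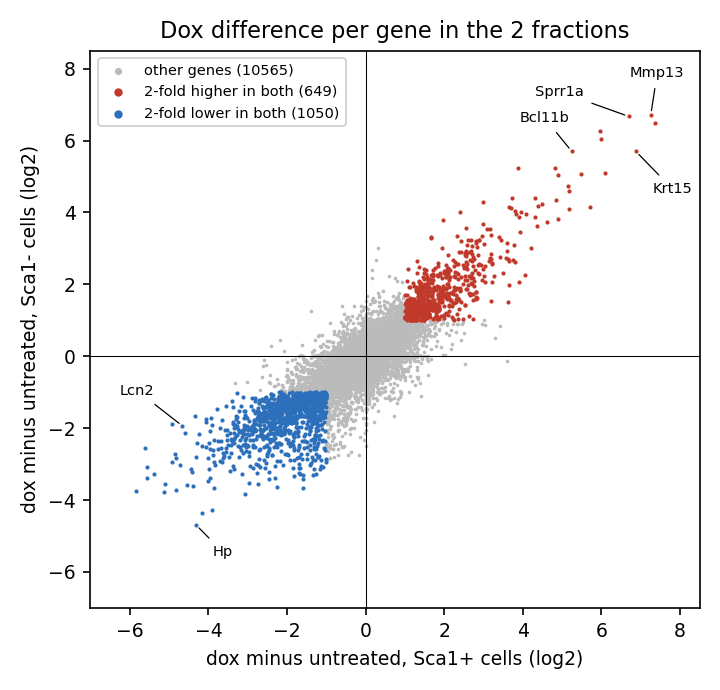
Dox minus untreated difference (log2) of each of 12264 genes in Sca1+ cells (horizontal axis) and in Sca1- cells (vertical axis). Red points are the 649 genes at least 2-fold higher in both fractions, blue points the 1050 genes at least 2-fold lower in both, and grey points all others; most genes lie along the diagonal.

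Cell-cycle genes were lower with dox. Of 26 S-phase genes, 17 were at least 2-fold lower in both fractions and none was higher, with median dox effects over the list of -1.22 in Sca1+ and -1.84 in Sca1- cells (each at percentile 0 of matched random lists). The cyclin gene Ccne2 (-1.68 in Sca1+, -3.27 in Sca1-), the ribonucleotide reductase gene Rrm2 (-1.84 and -3.10) and the origin-licensing genes Cdt1 (-1.83 and -2.62) and Cdc6 (-1.73 and -2.61) were among them. Of 29 G2/M genes, 13 were at least 2-fold lower in both fractions and 0 higher, with a median of -1.80 (percentile 0). The proliferation marker Mki67 was at -2.56 in Sca1+ and -3.12 in Sca1- cells (log2), Aurkb at -1.69 and -3.10, and Cdk1 at -1.33 and -3.31. A list of growth-arrest genes did not stand apart (median 0.12, percentile 67.7): 4 of 23 were higher in both fractions and 2 lower, with Ccng2 at 1.98 and 1.73, Ypel5 at 1.66 and 1.51, Mxi1 at 1.28 and 1.53, and Gas1 at -4.60 and -2.14. Across the 3 Gas1 probe sets the mean dox effect ran from -3.37 to -0.35. Targets of p53 went both ways (median 0.21, percentile 84.8), with Pmaip1 at 2.84 and 3.03 and Phlda3 16.0-fold and 7.06-fold lower. Ribosome-biogenesis genes had a median of -0.14 (percentile 6.32), and none of 19 was 2-fold different in both fractions.

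Genes of the ATF4 amino-acid response were lower with dox: all 17 had a mean dox effect below 0, 6 were at least 2-fold lower in both fractions, and the list median was -0.92 (percentile 0). Pck2 stood at -3.88 in Sca1+ and -2.75 in Sca1- cells, Psat1, a serine synthesis enzyme, at -2.70 and -2.59, and Trib3 at -2.57 and -1.56. ER chaperones (median -0.03, percentile 21.9), heat-shock genes (0.17, percentile 77.4) and respiratory-chain genes (0.01, percentile 15.5) did not stand apart, although Herpud1 was at -2.27 and -1.54. The hypoxia and glycolysis list was lower (median -0.50, percentile 0.26), with Vegfa at -2.89 and -1.16 and Ndrg1 at -2.39 and -1.95, while Pfkp was at 2.31 and 2.33. Cholesterol synthesis genes had a median of 0.10 (percentile 63.0).

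Interferon-stimulated genes were higher with dox: 15 of 26 were at least 2-fold higher in both fractions, 1 was lower, and the median was 1.21 (percentile 100). Oasl2 was higher by 2.75 in Sca1+ and 2.72 in Sca1- cells (log2), Ifit1 by 2.98 and 2.43, Ddx60 by 2.35 and 2.14, and Dhx58 by 2.64 and 1.72. MHC class I and antigen-processing genes did not stand apart (median -0.10, percentile 27.5), and the immunoproteasome gene Psmb8 was at -3.06 and -1.63. The NF-kB list had a median of -0.19 (percentile 8.85). Over the 7 genes with a highest array of 100 or more it was -1.14 (percentile 0.255). The stricter floor and the filter for genes above the authors' floor on all arrays each left 13 genes. Their medians of -0.33 (percentiles 7.66 and 6.005) did not stand apart. Cxcl1 was at -2.68 and -3.09, and Vcam1 was higher by at least 1.56 and at least 2.16. Immediate-early genes had a median of 0.04 (percentile 40.9). It was 0.54 (percentile 99.98) over 19 genes with a stricter floor and 0.39 (percentile 99.57) with a highest array of 100 or more. Over the 20 genes above the authors' floor on all arrays it was 0.04 (percentile 35.75). Egr2 was at 3.21 and 2.60, Dusp5 at 1.92 and 1.87 and Dusp4 at -1.97 and -1.63.

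Luminal genes were also lower with dox. Of 19 luminal genes, 7 were at least 2-fold lower in both fractions and 1 higher, with a median of -0.97 (percentile 0): Cldn7, a tight-junction protein, was at -2.80 and -2.30, Krt7 at -2.51 and -2.46, Krt8 at -1.73 and -1.96, and Wnt4 8.57-fold and 3.99-fold lower, while Muc1 was higher by at least 1.87 and at least 1.35. Of 17 basal and myoepithelial genes, 5 were lower in both and 0 higher, including Krt5 (15.9-fold and 8.76-fold lower) and the smooth-muscle actin gene Acta2 (-2.87 and -3.10). The basal list's median of -0.25 (percentile 2.19) lay within the middle range of random lists once low genes were left out or probe sets averaged, so only its named members are described as lower. Milk-protein genes had a median of -0.56 over 5 genes (percentile 8.96), and of -2.30 (percentiles 0.31 to 2.40) over the 2 left by each of the 3 stricter filters on low genes, with Ltf at -2.17 and -2.92. Mesenchymal genes went both ways (median 0.25, percentile 91.1): Zeb1 was at least 6.63-fold and at least 5.65-fold higher, Fn1 at 2.19 and 1.09, Postn at -3.05 and -1.68, and Cdh2 at -1.74 and -1.44. A second, dimmer Zeb1 probe set had a mean dox effect of only 0.22 (log2). TGF-beta and BMP targets had a median of -0.34 (percentile 2.36), led by Tgfbi (-5.55 and -3.39), Thbs1 (-3.89 and -2.62) and the repressor gene Id2 (-2.29 and -2.49), against Ltbp1 at 1.96 and 3.79. That list no longer stood apart under 5 of the alternatives (percentiles 2.59 to 7.745), so only its members are described. A second, dimmer Ltbp1 probe set had a mean dox effect of only 0.17 (log2). Wnt targets had a median of -0.31 over 9 genes (percentile 6.44), and of -1.87 over the 5 left by each filter on low genes, where they stood apart (percentiles 0.07 to 0.425). Notch genes did not stand apart (-0.25, percentile 8.45). Among these genes, Nkd2 was at -3.11 and -2.47, Apcdd1 at 2.71 and 2.66, and Notch1 at -1.92 and -1.67. The Ly6 family was lower (6 genes, median -1.51, percentile 0.04), although the 4 genes with a highest array of 100 or more did not stand apart (percentile 12.1), with Lypd3 at -4.29 and -2.41, and stem and progenitor surface genes had a median of -0.08 (percentile 17.3).

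Markers of other cell types gave little signal. Of the genes with a named probe set, 2 of 11 T-cell, 4 of 11 leukocyte, 4 of 10 fibroblast, 3 of 8 endothelial and 1 of 5 adipocyte markers passed the expression filter, with median dox effects of 0.26, 0.29, 0.47, 0.18 and -0.22 and percentiles of 69.2, 76.4, 93.9, 57.8 and 38.1. Dcn among the fibroblast markers, by the brighter of its probe sets, and Cd68 (2.79 and 2.40) among the leukocyte markers were at least 2-fold higher with dox in both fractions.

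The Sca1+ to Sca1- difference was smaller than the dox effect and had G2/M genes higher and luminal genes lower in Sca1+ cells. Without dox, 376 genes were at least 2-fold higher and 408 lower in Sca1+ cells; with dox, 309 were higher and 366 lower. In the same direction with and without dox, 132 were higher and 108 lower, against 9.47 and 12.2 for independent lists of these sizes and 0 to 8 in simulated arrays with noise alone. The Sca1 differences with and without dox correlated across genes with Pearson r = 0.47 and Spearman rho = 0.38. Centring on the median of all probe sets moved the share of higher genes without dox from 48.0% to 70.0%, and that of shared genes from 55.0% to 65.8%. No gene passed a Benjamini-Hochberg adjusted p of 0.05 for Sca1 in the additive limma fit, where 757 were higher and 922 lower at an unadjusted p under 0.05.

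Of 29 G2/M genes, 27 were at least 2-fold higher in Sca1+ than in Sca1- cells both with and without dox, with a median of 2.07 for the mean Sca1 difference (percentile 100). Hmmr, a spindle-associated protein, was higher by 1.63 (log2) without dox and 3.07 with dox, the centromeric histone gene Cenpa by 1.67 and 2.92, and the checkpoint kinase gene Bub1b by 1.25 and 3.25. S-phase genes were higher by a median of 0.68 (percentile 100), although none of 26 was 2-fold higher both times; Ccne2 stood at 0.88 and 2.48. Most of the 12 named genes higher in Sca1+ cells act in mitosis: Mastl was higher by 1.79 without and 2.60 with dox (log2), Ckap2 3.40-fold and 7.79-fold higher, Espl1, the separase, 3.35-fold and 4.71-fold, and Kif2c 3.27-fold and 10.0-fold, with Kifc1, Racgap1, Kif20a and Kif20b between 3.12-fold and 3.41-fold higher without dox. Across the 4 Kif2c probe sets the mean Sca1 difference ran from 0.14 to 2.52 (log2). The other named genes were Sostdc1, a BMP and Wnt antagonist (3.59-fold and 4.87-fold), the heparin-binding growth factor gene Ptn (3.17-fold and 3.72-fold) and the Ly6-family gene Ly6e (5.77-fold and 3.16-fold). The mean Sca1 differences of the 3 Ptn probe sets ran from 0.21 to 1.92 (log2), and a second, dimmer Ly6e probe set gave 0.73. The Ly6 family had a median of 0.66 (percentile 99.95), with Ly6d at 3.05 without dox and 0.73 with it. Its median was 1.36 over the 4 genes left by each filter on low genes and 0.30 over 8 genes without a floor, and it stood apart each time. Serpinb1a (at least 12.9-fold) and the defensin gene Defb1 (at least 9.13-fold) were the highest single genes without dox, and Depdc1a (12.9-fold) the highest with dox. A second, dimmer Serpinb1a probe set had a smaller mean Sca1 difference of 0.52 (log2).

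Genes lower in Sca1+ cells included Igfbp5, an IGF-binding protein, at 26.5-fold without and 12.7-fold with dox. A second, dimmer Igfbp5 probe set had a smaller mean Sca1 difference of -1.20 (log2). The cartilage collagen genes Col2a1 (6.81-fold and 7.69-fold) and Col9a1 (12.5-fold and 6.80-fold), the channel genes Kcne3 (8.74-fold and at least 8.95-fold) and Ano1 (6.37-fold and 6.88-fold), the peptide transporter gene Slc15a2 (16.1-fold and at least 8.19-fold), Chil1 (8.58-fold and 6.70-fold) and Hp (7.54-fold and at least 5.78-fold) were also lower. Across the 3 Slc15a2 probe sets the mean Sca1 difference ran from -3.52 to -0.64 (log2). Ltbp2, Krt7, Chrnb1 and Plscr2 were between 4.88-fold and 10.3-fold lower without dox. Of 19 luminal genes, 8 were at least 2-fold lower in Sca1+ cells both times and 0 higher, with a median of -1.17 (percentile 0): Elf5, an alveolar transcription factor, was at -2.18 without dox and at the floor in dox-treated Sca1+ cells (-1.70 as a bound), Aldh1a3 at -2.17 and -1.47, and the receptor gene Kit at -2.26 and -1.02. A second, dimmer Kit probe set had a mean Sca1 difference of 0.19. Milk-protein genes had a median of -0.51 (5 genes, percentile 1.51), which did not stand apart with probe sets averaged (percentile 3.81). Basal genes had a median of 0.25 (percentile 99.99), with only Trp63, the basal-cell transcription factor p63, 2-fold higher both times (1.36 and 1.08).

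Signalling lists were mostly lower in Sca1+ cells. The medians were -0.48 for Notch genes (percentile 0.01, and 10.4 without a floor), with Dtx1 at -2.15 and -0.88 and Nrarp at -1.89 and -0.90; -0.54 for TGF-beta and BMP targets (percentile 0), with Ltbp2 at -3.37 and, as a bound, -2.46, and Id2 at -1.83 and -1.62, against Ltbp1 at 2.68 and 0.85 and Tgfbi at 2.00 and -0.16; -0.51 for immediate-early genes (percentile 0), with Dusp4 at -1.56 and -1.89 and Egr3 at -1.36 and -1.28; and -0.40 for NF-kB genes (percentile 0), with Lcn2 at -2.14 and -4.86 and Cxcl1 at -2.52 and -2.12. Second, dimmer probe sets of Dtx1 and Ltbp1 had mean Sca1 differences of 0.10 and 0.17. ER chaperones (-0.21, percentile 0.49) and respiratory-chain genes (-0.09, percentile 1.88) lay slightly below 0, but no longer stood apart with probe sets averaged (percentiles 6.56 and 10.1). ATF4 targets lay slightly above 0 (0.32, percentile 100). Cholesterol synthesis genes had a median of 0.65 without dox (percentile 100) and -0.03 with dox (percentile 58.9), and of 0.30 over both (percentile 100). Growth-arrest genes had a median of 0.09 (percentile 98.4), which did not stand apart under 4 of the alternatives (percentiles 75.6 to 95.1). None of the members of these 5 lists was 2-fold different in the same direction both times. Mesenchymal genes had a median of 0.17 (percentile 98.7), but lay in the lowest range with the stricter floor (-0.25, percentile 0.485) and with a highest array of 100 or more (-0.37, percentile 0.035). The list stood apart in neither direction under 3 other alternatives (percentiles 57.0 to 87.8), so no direction is given for it, and Sparc stood at 2.17 and 1.17. Interferon-stimulated genes had a median of -0.18 (percentile 4.45), with -0.32 without dox (percentile 0.03) and -0.07 with dox (percentile 50.7). Hypoxia genes stood apart in opposite directions, with a median of 0.19 without dox (percentile 99.3) and -0.19 with dox (percentile 1.53). Wnt targets had a median of -0.02 (percentile 54.9), and of -0.59 (percentiles 0.15 to 0.44) under each filter on low genes. Of the other lists, p53 targets had a median of -0.02 (percentile 56.1), ribosome-biogenesis genes 0.03 (percentile 83.7; Rrp9 was at -1.97 and -1.79), MHC class I genes 0.00 (percentile 69.8), heat-shock genes 0.00 (percentile 61.95) and stem and progenitor surface genes -0.06 (percentile 30.4). The T-cell, leukocyte, fibroblast, endothelial and adipocyte markers had medians of -0.08, 0.06, 0.06, 0.17 and 0.53, at percentiles 44.9, 69.4, 68.1, 75.8 and 88.65.

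**Figure D3:**
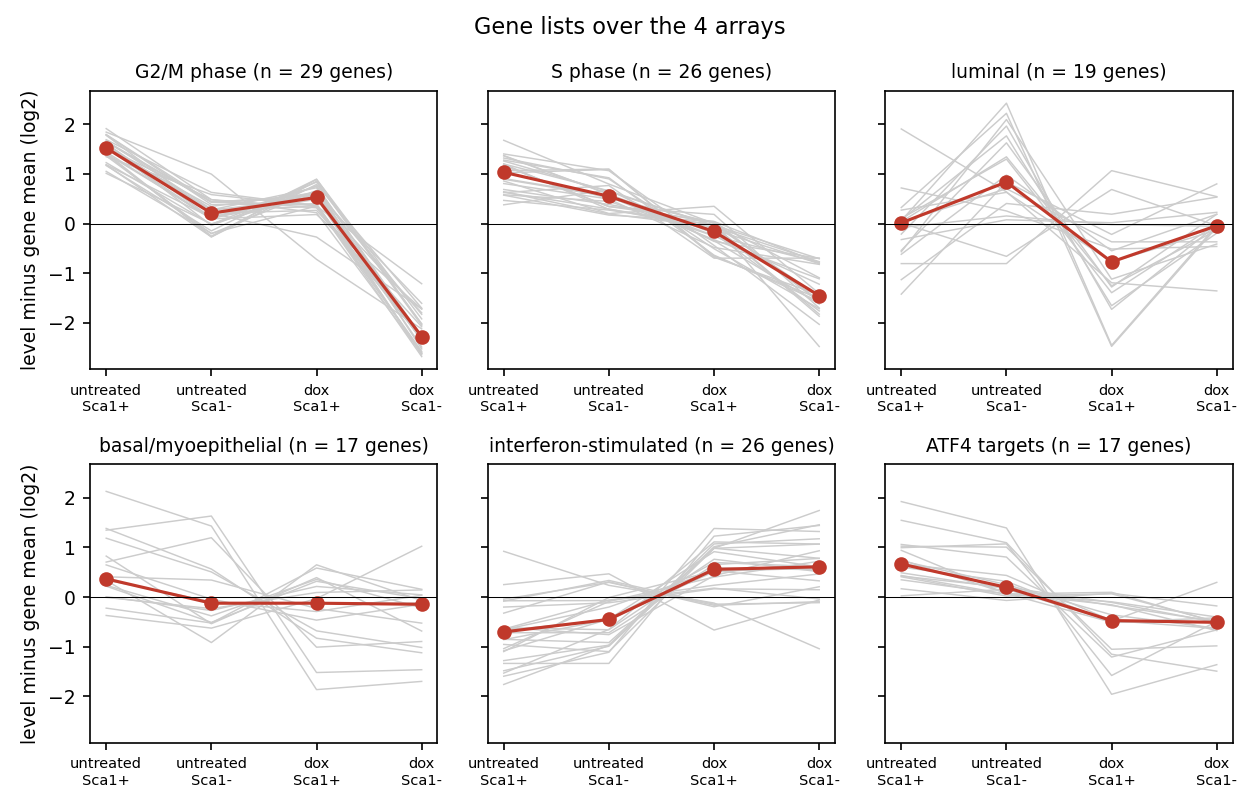
Levels of 6 gene lists on the 4 arrays (horizontal axis), each gene as a grey line of its log2 level minus its own mean (vertical axis) and the list median as red points. The G2/M median is highest in untreated Sca1+ cells and lowest in dox Sca1- cells, and the interferon-stimulated median is higher on both dox arrays.

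The dox effects of some gene groups had different sizes in the fractions, a difference that was not tested. G2/M genes had a median dox effect of -0.99 (log2) in Sca1+ cells and -2.39 in Sca1- cells, with a median difference of 1.48 between the dox effects (percentile 100), and S-phase genes -1.22 and -1.84 (difference 0.70, percentile 100). Cholesterol synthesis genes had a median dox effect of -0.22 in Sca1+ and 0.42 in Sca1- cells (difference -0.63, percentile 0), with Mvd at 0.23 and 1.54. Basal genes had medians of -0.49 in Sca1+ and 0.00 in Sca1- cells (difference -0.34, percentile 0). Mesenchymal genes had -0.04 and 0.52 (difference -0.34, percentile 0.26). The difference also stood apart for the Ly6 (-0.78, percentile 0.16), hypoxia (-0.20, percentile 0.86) and heat-shock lists (-0.05, percentile 1.70). In the other direction were the Notch (0.31, percentile 99.38) and interferon-stimulated lists (0.23, percentile 99.83). How these list differences depend on the processing was not examined. Single genes with the largest differences were Mgp, the matrix Gla protein, with dox differences of 3.59 in Sca1+ and -0.14 in Sca1- cells, and Il6, Rgs2 and Ptprz1, which were 9.76-fold, 10.7-fold and 5.75-fold higher with dox in Sca1+ cells and read 0.52, 0.85 and -0.21 (log2) in Sca1- cells. These 4 genes read about alike in dox-treated cells of both fractions, between 0.05 and 0.34 apart. Prom1 was 6.71-fold lower with dox in Sca1- cells and near the floor in Sca1+ cells with and without it. In the other direction, Tubb6 (-5.62 in Sca1+ and -2.55 in Sca1-), Bbox1 (-4.93 and -1.88) and Lcn2 (-4.66 and -1.94) were lower with dox by more in Sca1+ cells. Plxdc1 was at -2.42 and 0.29, and Gas6, a ligand of TAM receptors, at 0.32 and 3.02. For Tubb6 and Plxdc1 a second, dimmer probe set gave differences of the opposite sign.

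In all, the dox effects of the fractions differed by 2-fold or more for 452 genes upward and 422 downward in Sca1+ relative to Sca1- cells. Simulated arrays with noise alone gave 631 to 749 such genes in all, against 874 observed, and that noise was itself estimated from these differences, so the counts do not set the interaction apart from noise. Centring on the median of all probe sets moved the share upward from 51.7% to 24.7%, and centring on probe sets of a mean level of 100 or more moved it to 61.2%. The SD over genes of the mean dox effect was 0.90 and that of the mean Sca1 difference 0.44, against 0.27 for the difference of the dox effects divided by 2, which has the same array noise.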

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

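Genes whose difference pointed in opposite directions in the 2 settings, by 2-fold or more in each, were singled out; with 1 array per group the difference itself was not tested. The dox difference of Srms was 1.41 (log2) in Sca1+ cells and -1.09 in Sca1- cells, and these were 2.503 apart. Gfra3 went from -1.39 to 1.26, a difference of -2.65, and had the corresponding opposite Sca1 differences of 1.39 without and -1.26 with dox. Opposite Sca1 differences were also seen for Gas1 (1.42 without and -1.04 with dox; dox effects -2.46 apart), Nfatc1 (1.22 and -1.01; -2.24 apart), Pnmt (1.26 and -1.37; -2.63 apart) and Sry (-1.03 and 1.10; 2.13 apart). Of 12264 genes these are 2 for dox and 5 for Sca1. Simulated arrays with noise alone gave 0 to 9 genes for dox and 0 to 8 for Sca1 in the same direction. Opposite directions were not counted there, so the 2 and 5 are not set apart from noise. An array at the authors' floor enters the values of Srms, Gfra3, Pnmt and Sry, so for them at least 1 of the differences is a bound.

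Probe sets without a single gene symbol were outside the comparisons. Of 3636 that passed the same filter, 131 were at least 2-fold higher and 104 at least 2-fold lower with dox in both fractions, against the untreated arrays.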

How the results depend on the processing

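The alternatives with a highest array of 100 or more, with every array above the authors' floor and with centring on probe sets of a mean level of 100 or more were chosen after seeing the data; all others were planned. Each group has only replicate number 1, so no replicates could be paired. The additive limma fit does compare dox within each Sca1 fraction and Sca1 within each treatment, with 1 residual degree of freedom. No array could be left out, since each group has 1. Pseudocount alternatives were not run, since values were already on the log2 scale. Of the medians of lists with at least 5 genes, 338 kept their call or their lack of one, 19 lost a call and 11 gained one. Another 4, of lists that stood apart in the main setting, changed sign. Sign changes of lists that had not stood apart were not counted. Centring moves all genes of an array alike and so hardly moves percentiles. Of the counts, 92 stayed within 1.5 times, 14 of them without a floor, and 66 did not. Of the correlations, 27 stayed within 0.05, and 9 did not. Of the named-gene values, 248 stayed within array noise, 52 moved further in the same direction or toward 0, and 3 changed sign. Quantile normalization and each centring kept all 68 values compared, but they shift genes little and could hardly fail. With probe sets averaged, 41 stayed and 27 moved. With the second probe set, 3 stayed, 25 moved and 3 changed sign. Quantile normalization kept 1644 of the 1699 shared dox genes and 228 of the 240 shared Sca1 genes. Leaving out the floor changed no count, since a gene below it on every array cannot differ 2-fold, so that alternative says nothing about the counts. The arrays' floor limits what can be seen of low genes, and where not stated the cause of a change was not tested.

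In the order higher then lower, with every probe set on its own, which takes more features, there were 1804 and 2481 for dox in Sca1+ cells, 1526 and 2204 in Sca1- cells, 1045 and 1602 shared, 617 and 698 for Sca1 without dox, 494 and 569 with dox, 209 higher shared, and 835 and 743 for the difference of the dox effects. With a highest array of 100 or more, which takes fewer genes, they were 579 and 1042, 530 and 893, 417 higher shared, 223 and 177, 196 and 236, and 161 and 210. Under the 1.5-fold rule they were 2350 and 2549, 2059 and 2378, 1448 and 1835 shared, 1039 and 1106, 845 and 1102, 358 and 347 shared, and 1222 and 1295. Under the 3-fold rule they were 409 and 802, 346 and 654, 254 and 432 shared, 71 and 152, 143 and 85, 18 and 36 shared, and 113 and 77. The additive limma fit gave 1460 and 1817 for dox and 0 and 0 for Sca1, where 757 and 922 had an unadjusted p under 0.05. Centring on the median of all probe sets gave 643 higher for Sca1 without dox, and 260 and 792 for the difference of the dox effects. The stricter floor gave 246 lower for Sca1 without dox and 225 higher for the difference of the dox effects, and genes above the authors' floor on all arrays gave 260 and 266 for these. The mean of a gene's probe sets gave 232 lower for Sca1 with dox, 71 lower shared, and 300 higher for the difference of the dox effects.

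The Pearson r and Spearman rho across genes between the dox effects were 0.90 and 0.90 with a highest array of 100 or more, where those between the Sca1 differences were 0.60 and 0.50. The stricter floor gave a rho of 0.86 for dox, and 0.56 and 0.47 for Sca1. Genes above the floor on all arrays gave an r of 0.52 for Sca1, and without a floor rho was 0.73 for dox. The basal list's dox median was -0.057 with the stricter floor, -0.057 over genes above the floor on all arrays, -0.25 with a highest array of 100 or more and -0.23 with probe sets averaged, within the middle range of random lists each time. The interferon-stimulated list's Sca1 median passed into the lowest range at -0.18 after quantile normalization and -0.19 over genes above the floor. The mesenchymal Sca1 median changed sign, to -0.25 with the stricter floor, -0.37 with a highest array of 100 or more and -0.017 over genes above the floor. The respiratory-chain Sca1 median was 0.018 with centring on the median of all probe sets. With probe sets averaged, the luminal medians shrank to -0.46 for dox (percentile 0.19) and -0.72 for Sca1 (percentile 0), and still stood apart. Calls of other lists also depended on a setting: for dox those of TGF-beta targets, the Ly6 family and the pair Bcl11b and Bcl11a were lost, and those of the Wnt, NF-kB, immediate-early, milk-protein and fibroblast lists gained, the last over 1 gene. For Sca1 the growth-arrest, ER-chaperone, respiratory-chain, milk-protein and Notch calls were lost and the Wnt call gained. The second probe set gave a mean dox effect of -2.51 for Bcl11b, and differences of the dox effects of 0.41 for Tubb6 and 0.64 for Plxdc1.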

Other observations

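The tests on the Bcl11b probe sets, the cell-cycle lists and the ATF4 targets were chosen after those results were seen, as were the filters applied below to list members not yet examined. The 3 tests on those members were set before their values were seen. Cornified envelope genes whose values had not been seen before the test (18 passing the filter) had a median dox effect of 0.33 (percentile 98.16). Of these, 2 were at least 2-fold higher in both fractions and 2 lower. The medians were 0.42 in Sca1+ (percentile 97.3) and 0.05 in Sca1- cells (percentile 73.0). Of the 18, 7 were at the floor on both untreated arrays and so could not be lower with dox, and the other 11 had a median of 0.10. The 6 above the floor on all arrays had 0.44 (percentile 94.5), and the 5 passing the stricter floor -0.11 (percentile 36.8). Neuronal genes other than Ina, Gng4, Eno2, Uchl1 and Dpysl3, which had been noticed among high-ranking dox genes, had a median of 0.36 over 21 members (percentile 98.86), with 6 at least 2-fold higher in both fractions and 1 lower. Of the 21, 8 were at the floor on both untreated arrays, and the other 13 had a median of 0.08. The 10 above the floor on all arrays had 0.05 (percentile 56.2). The list's median was 0.72 in Sca1+ (percentile 100) and 0.13 in Sca1- cells (percentile 81.3), and the median difference between fractions was 0.22 (percentile 88.4), which did not stand apart. Whether either pattern extends beyond the genes noticed first therefore stays open.

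Cartilage genes other than the collagens noticed first had a median Sca1 difference of -0.25 over 13 members (percentile 1.32), with none 2-fold lower both times. Their median was -0.26 without dox (percentile 3.23) and -0.35 with dox (percentile 0.325). The 11 above the floor on all arrays had -0.25 (percentile 2.26), and the 7 with a highest array of 100 or more had -0.25 (percentile 2.985), just outside the lowest range. The stricter floor gave -0.46 over 9 members (percentile 0.01), and probe sets averaged gave -0.32 (percentile 0.20). Without a floor the median was 0. This remains a hypothesis from 1 array per group.

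The Bcl11b probe sets went apart with dox. The other 3 probe sets had a mean dox difference of -1.69 (log2), which is -8.55 in units of the noise SD of that mean. That noise comes from other genes and does not describe these probe sets, whose own dox differences were unequal between the fractions by -3.36, -1.58 and -1.54, so array noise stays open. It does not include differences between cultures, and 2 of the 3 probe sets read close to the floor with dox in both fractions. A candidate explanation is that the induced transcript carries only the part of Bcl11b read by 1450339_a_at while the cell's own transcript is lower. That 0 of the other 3 probe sets were 2-fold higher in either fraction had been seen before this was proposed, so it is no test of it. The positions of the probe sets on the transcript were not examined here, so which part each reads stays open.

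The cell-cycle lists were lower with dox and higher in Sca1+ cells. The G2/M median dox effect was -1.78 after quantile normalization. That check could hardly fail, because the array medians were already close. Among probe sets with a mean level of 100 or more they ran from 8.20 to 8.24. It therefore does not decide on scaling between arrays. Loss of low values at the floor is argued against by 0 of the 29 G2/M members being at the floor on any array. The 3' minus 5' differences of actin and Gapdh were lowest on the untreated Sca1+ array (0.69 and -0.10). They were highest on the dox Sca1- array (0.91 and 0.11). These arrays had the highest and the lowest G2/M median. The arrays between them did not follow this order. Dox Sca1+ lay above untreated Sca1- in actin (0.83 and 0.81) and in Gapdh (-0.013 and -0.055). Yet its G2/M genes had a median of -0.99 against untreated Sca1+, which itself lay 1.32 above untreated Sca1-. A part played by RNA quality was not tested. A difference between the treated and untreated cultures other than dox cannot be told apart from dox, because there is 1 array per group. That could not account for the Sca1 difference seen within each treatment, where the sort itself, which selects on a surface marker, stays open as a source.

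No array holds a control for the drug itself, so its own effects stay open. One route, inhibition of mitochondrial translation, would come with higher ATF4 targets. Their median dox effect was -0.92, so no net rise was seen. That value was known when the test was chosen. Without a drug control, a rise masked by other effects cannot be excluded, so this route stays open too. Other effects of dox were not tested.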
